A study of Macaca mulatta with 8 samples.

How the data were processed

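Blood mononuclear cells of rhesus macaques were cryopreserved, thawed on the same day, enriched magnetically for CD4-positive cells and sorted into 4 populations on each of 2 days, per the labels' protocols. Libraries were made with the 10x 3' version 2 chemistry, per the labels, and Cell Ranger 2.1.1 is named per the submitters' processing notes. The genome build and annotation are not given in the sources used here. The deposited values are whole counts of UMIs per gene and cell, with no scaling by the authors that the files record, and the authors' per-cell UMI totals equal the column sums for 25397 of 25397 cells. The table held 16429 genes, of which 154 were at 0 in every cell. Besides the counts, the authors deposited for each cell its library, day, cluster number (10 clusters), class (3 classes) and, for 7515 cells, 1 of 7 finer names, without stating the method. The lowest cell had 817 UMIs, and mitochondrial shares ended just under 5% in each library (4.98 to 5.00% at most), so the cells seem to have been filtered on both before deposit, although no label states a filter.

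Cells were assigned to libraries by the deposited library names, and 0 columns went unused. Of 3130 identifiers without a symbol in the file, 309 were named from the reference table of gene identifiers, and 3146 genes, including LOC names, were left unnamed. Where a symbol had several identifiers, the one with the most UMIs was used. Raw counts were summed over all cells of each library, which gave 2992787 to 12149559 UMIs per library, and divided by the library total. Ratios are log2 ratios of CPM with a pseudocount of 10 CPM, which understates the change of low genes. With 1 library per population and day there were no replicates, and no test was run. Exact Poisson intervals were given for summed counts and exact binomial (Clopper-Pearson) intervals for shares of cells, at 95%, and both cover counting error only. All cells were kept, no doublet caller was run, and no cells were clustered, since the authors' annotation was used. Cells with at least 3 UMIs of red cell, B cell, monocyte or platelet markers, or with over 2 times the library's median UMIs, numbered 1059 and were left out in an alternative. They comprised 563 cells with red cell, 132 with B cell, 21 with monocyte and 1 with platelet markers and 407 with high UMIs, and some cells met more than 1 of these.

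A gene was called higher or lower between populations where the ratio was at least 2-fold the same way on both days, with at least 50 CPM in 1 compared library on each day, and between days where it was at least 2-fold with at least 50 CPM on 1 day. The text names the 12 such genes per direction with the largest smaller ratio of both days, and for days the 10 with the largest difference per direction, without unnamed, mitochondrial and ribosomal protein genes, and members of the gene lists as examples. Of the genes that this rule names for transferred against conventional cells, 1 is not reported here. Comparisons, calling rule, 30 gene lists (380 members, 305 found in the table), cell type markers and most alternatives were fixed before the data were examined. The p53 target list was added afterwards. Sort marker genes stayed in the lists. IL2RA was in Treg core and in IL-2 and STAT5 response, and IL7R in naive and quiescent T cell. A list's median log2 ratio was taken over members with at least 20 CPM where at least 3 were measured. It was set against 10000 random lists of the same size matched on mean expression, each drawn from the 100 nearest genes, and called apart outside the central 95% (percentiles 2.5 to 97.5), which describes these libraries and is no test. The lists were Treg core, naive and quiescent T cell, T helper cytokines and CD40LG, cytotoxic, Th1, Th2, Th17, Tfh, proliferation, activation and effector memory, immediate early response, MHC class II, IL-2 and STAT5 response, interferon response, pro-apoptotic, anti-apoptotic, glycolysis, oxidative phosphorylation, homing and trafficking, co-inhibitory receptors, heat shock, and markers of monocytes, B, NK, CD8 T, dendritic, gamma delta T and T cells, platelets and red cells.

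The alternatives fixed beforehand were TMM factors (edgeR 4.0.16), median-of-ratios size factors (DESeq2 1.42.0), pseudocounts of 1 and 30 CPM, no filter on expression, the mean of per-cell CPM, leaving out doublet-like cells, thinning library totals to 2992787 UMIs, list means in place of medians, Pearson correlation, a 3-fold signature, and thinning each cell to 1000 UMIs. Added after the data were seen were the authors' matching classes, scaling on named genes without ribosomal, mitochondrial and hemoglobin genes, and similarity over those named genes. Median-of-ratios and TMM factors were used for scaling only. All-gene medians cover genes at 50 CPM or more in a compared library. Where a scaling is said to move such a median, the value is the median shift per gene. That shift was taken over genes at 50 CPM or more in the counts of all libraries together. Analyses ran in Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9, and in R 4.3.3. Calling was tested on simulated counts drawn from the real library means over 16429 genes, with 100 genes changed by a log2 of 2 and 100 by 1.5. For transferred against endogenous cells 98 and 99 of these were recovered, for transferred against conventional cells 97 and 98, for endogenous against conventional cells 100 and 96, and for the CD127-positive sorts 99 and 98. Of 1726, 1699, 1583 and 1520 unchanged genes in these comparisons, 0 were called. The simulated libraries of a comparison shared an averaged profile and differed only by the set changes and counting noise. Other differences between libraries were not simulated, so these values do not give the share of false calls in the real data. For transferred against endogenous cells, 11 of 200 unshifted lists of 15 members fell outside the central 95%, and 10 of 10 lists with every member doubled lay above it, over 3857 genes.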

Results

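Regulatory T cells (Tregs) are CD4-positive T cells that restrain immune responses, and the series followed such cells in macaque blood after adoptive transfer, by droplet-based single-cell RNA sequencing on day 3 and day 20. CFSE is a dye that cells keep and dilute at each division, and the CFSE-positive sort is taken here, from the series title, as the transferred cells. The other 3 sorted populations were CD25high CD127low cells, which have the surface phenotype of endogenous Tregs, CD127-positive CD25-positive cells, and CD127-positive CD25-negative cells, the conventional CD4 phenotype. Each population gave 1 library on each day, so there were 8 libraries and no replicates, and no p-values were computed. Every interval given is a 95% interval that covers counting error only. The labels name neither the animal nor any treatment behind a library. Values are CPM, the usual scaling of UMI (counted RNA molecule) counts to a common library total, of the counts summed over all cells of a library.

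The 8 libraries held 25397 cells and 67627232 UMIs. The CFSE-positive libraries had 4142 cells and 12149559 UMIs on day 3 and 1149 cells and 2992787 UMIs on day 20. In the CD25high CD127low sort there were 3347 cells and 10789317 UMIs on day 3 and 2343 cells and 6579896 UMIs on day 20. CD127-positive CD25-positive cells gave 2951 cells and 8945900 UMIs on day 3 and 4751 cells and 10488609 UMIs on day 20. The CD127-positive CD25-negative libraries held 3037 cells and 7542889 UMIs on day 3 and 3677 cells and 8138274 UMIs on day 20. Median UMIs per cell lay between 2131 and 3095. HBB, the beta chain of adult hemoglobin and a red cell transcript, stood at 503, 1385, 147 and 316 CPM in the CFSE-positive, CD25high CD127low, CD127-positive CD25-positive and CD127-positive CD25-negative libraries of day 3. On day 20 it was at most 0.668 CPM in any of the 4 libraries. HBA2, the alpha chain, did not share that pattern, at 228 CPM on day 3 and 143 CPM on day 20 in the CFSE-positive libraries.

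Transferred cells were compared with CD25high CD127low cells to ask how far their expression matched that of endogenous Tregs. FOXP3 (ENSMMUG00000008624), which encodes the transcription factor that defines Tregs, was higher in CFSE-positive cells, at 259 CPM (249.6 to 268) against 76.0 CPM (70.9 to 81.4) on day 3. On day 20 the same gene stood at 127 CPM (115 to 140.4) against 67.8 CPM (61.6 to 74.4) in the whole sorts. Between the authors' transTreg class of CFSE-positive and endoTreg class of CD25high CD127low cells, FOXP3 was 259.6 CPM (251 to 269) against 160.2 CPM (149 to 172) on day 3. On day 20 these classes had 132 CPM (118 to 146) against 139.9 CPM (126 to 155), with overlapping intervals. S100A4 (ENSMMUG00000010979), a calcium-binding protein of effector and memory T cells, was lower in transferred cells, at 323 CPM (313 to 333) against 2044 CPM (2017 to 2071) on day 3 and 169 CPM (155 to 184) against 2259 CPM (2223 to 2296) on day 20. ITGB1 (ENSMMUG00000017767), an integrin chain of memory T cells, stood at 26.8 CPM (24.0 to 29.9) against 313 CPM (303 to 324) on day 3, and ANXA1 (ENSMMUG00000012667), a regulator of inflammation, at 47.2 CPM (43.5 to 51.3) against 479 CPM (466 to 492).

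Of 1851 genes that reached 50 CPM in a compared library on each day, 7 were at least 2-fold higher and 23 at least 2-fold lower in transferred cells on both days. The all-gene median log2 ratio, over genes at 50 CPM or more in a compared library on that day, was 0.41 on day 3 (2199 genes) and 0.05 on day 20 (1963 genes). Under TMM scaling the all-gene median on day 3 moved by -0.31, with 3 genes higher and 30 lower, as with median-of-ratios factors, while named-gene scaling gave 3 and 28. In cells of the authors' matching classes 10 were higher and 22 lower, with 4 of the 7 and 16 of the 23 kept. On day 20 these classes put CST3 at 0.14, HEBP2 at 0.94 and CD69 at -0.75, and IGKC was likewise under 2-fold. The list results are therefore given beside random lists drawn from the same libraries. The named genes higher on both days were SFR1, a recombination repair cofactor, ABI2, an actin regulator, HEBP2, a heme-binding protein, CST3, a protease inhibitor of myeloid cells, and PLAC8, MLLT11 and IGKC. SFR1 had log2 ratios of 1.30 on day 3 and 1.42 on day 20. PLAC8, MLLT11 and IGKC were under 2-fold on at least 1 day with TMM factors. IGKC is an immunoglobulin light chain of B cells, and the B cell marker CD79A stood beside it at 55.4 CPM in CFSE-positive and 20.2 CPM in CD25high CD127low cells on day 3.

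IL7R (ENSMMUG00000001676) encodes CD127, a marker used to sort the other populations, and was 13.4 CPM (11.4 to 15.6) in transferred cells against 404 CPM (392 to 416) in CD25high CD127low cells on day 3. The authors' Tconv class held 60.9% of the latter sort on that day. Between the matching classes IL7R differed less, at 11.8 CPM (9.91 to 13.9) in transTreg and 145 CPM (134 to 157) in endoTreg cells. The 12 lower genes named by rule also included PLA2G16, a phospholipase, GPR183, an oxysterol receptor that guides T cell migration, RGS1, which dampens chemokine receptor signalling, and CD69, an early activation antigen. MT1M, a metallothionein that binds zinc, PRSS57, a serine protease, GPRIN3, a G protein partner, and TESC, a calcium-binding protein, completed them. GPR183 had log2 ratios of -3.17 and -2.65 on day 3 and day 20, RGS1 of -2.42 and -1.73, and CD69 of -1.32 and -1.29. All 12 stayed at least 2-fold lower on both days under TMM, median-of-ratios and named-gene scaling.

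Treg core genes were higher as a list in transferred cells on day 3, with a median log2 ratio of 0.59 (random median 0.39, percentile 97.6) and 4 of 15 measured members at least 2-fold higher and 0 at least 2-fold lower. Examples were FOXP3 at 1.64, LRRC32, which presents latent TGF-beta on Tregs, at 1.73, and IL2RA, which encodes the sort marker CD25, at 0.98. Between the transTreg and endoTreg classes of day 3 IL2RA was close, at 639 CPM (624 to 653) against 597 CPM (574 to 620.0). In these matching classes alone the Treg core median on day 3 was 0.14, and on day 20 it was -0.17 (random median 0.06, percentile 0.36) with all cells. CTLA4, a checkpoint receptor of Tregs, was lower in transferred cells on both days, at 37.5 against 49.4 CPM on day 3 and 24.4 against 47.7 CPM on day 20. The gap was wider between the matching classes, but these keep unlike parts of their sorts. The endoTreg class held 38.9% of CD25high CD127low cells on day 3 and 40.0% on day 20. The transTreg class held 98.5% and 92.6% of CFSE-positive cells. Part of the wider gap may therefore come from the choice of cells. On day 3 CTLA4 was 37.4 CPM (34.0 to 41.0) in transTreg and 83.4 CPM (75.1 to 92.3) in endoTreg cells. On day 20 these classes had 25.5 CPM (19.9 to 32.1) and 88.2 CPM (77.3 to 100). Naive and quiescent genes were lower on day 3, at -0.47 (random median 0.40, percentile 0.01) with 1 of 11 measured members at least 2-fold higher and 5 at least 2-fold lower, among them TCF7 at -1.37 and LEF1 at -1.39, both transcription factors of naive T cells. TCF7 differed less between the matching classes, at 37.7 CPM (34.3 to 41.3) in transTreg and 55.1 CPM (48.3 to 62.4) in endoTreg cells. Interferon response genes were lower on day 3 at -0.51 (random median 0.37, percentile 0) and on day 20 at -0.39 (random median 0.03, percentile 0), with MX1, an antiviral GTPase, at -1.49 and -1.10, although the day 20 list was within the central 95% in matching classes (percentile 3.88). Homing genes were lower on day 3 at -0.39 (random median 0.40, percentile 0.1), including ITGB1 at -3.13. Members went both ways, with 2 of 9 measured members at least 2-fold higher and 3 at least 2-fold lower. Immediate early genes were lower on both days, at -0.63 (random median 0.47, percentile 0.78) and -0.60 (random median 0.07, percentile 0.22), over 3 measured members.

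On day 20 activation and effector memory genes were lower in transferred cells, at -0.66 (random median 0.03, percentile 0) with 0 of 13 measured members at least 2-fold higher and 5 at least 2-fold lower, including S100A4, ITGB1 and ANXA1. The IL-2 and STAT5 response list was lower at -0.50 (random median 0.06, percentile 0), with BCL2, an anti-apoptotic protein, at -2.40 and CISH, a feedback inhibitor of cytokine signalling, at -1.27. CISH was 20.8 CPM (15.8 to 26.9) in transTreg and 37.9 CPM (30.9 to 46.0) in endoTreg cells on day 20, under 2-fold. Th17 genes were lower at -1.12 (random median 0.07, percentile 0.75) over 3 measured members, among them RORA, a nuclear receptor, at -1.12. Cytotoxic genes were lower at -0.40 (random median 0.04, percentile 0.98), while T cell markers were higher at 0.27 (random median 0.03, percentile 99.4). The cytotoxic call was lost without doublet-like cells (percentile 10.7) and that of T cell markers in matching classes (percentile 62.0). Pro-apoptotic genes were higher on both days, at 1.08 (random median 0.39, percentile 99.5) and 0.46 (random median 0.03, percentile 99.2) over 3 measured members, with BAX, which permeabilises mitochondria, at 894 CPM (878 to 911) against 140.4 CPM (133 to 148) on day 3. In cells of the authors' matching classes the pro-apoptotic median was 0.81 (percentile 98.8) on day 3 and 0.12 (percentile 78.3) on day 20, the latter within the central 95%. A list of p53 targets, chosen after BAX had been seen, was higher on day 3 at 1.08 (random median 0.35, percentile 100) with 6 of 9 measured members at least 2-fold higher and 0 at least 2-fold lower and on day 20 at 0.24 (random median 0.05, percentile 98.3). CDKN1A, a cell cycle inhibitor, was at 1.51 on day 3. The p53 and pro-apoptotic lists share BAX and FAS, and FAS, at 1.08, was the median member of both on day 3. These results are therefore not independent, and BAX was kept in the p53 list in every comparison. Anti-apoptotic genes lay within the central 95% of random lists on both days, at 0.16 (random median 0.36, percentile 13.2) and -0.14 (random median 0.06, percentile 12.3), and oxidative phosphorylation genes at 0.44 (random median 0.39, percentile 67) and 0.07 (random median 0.03, percentile 75).

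**Figure D1:**
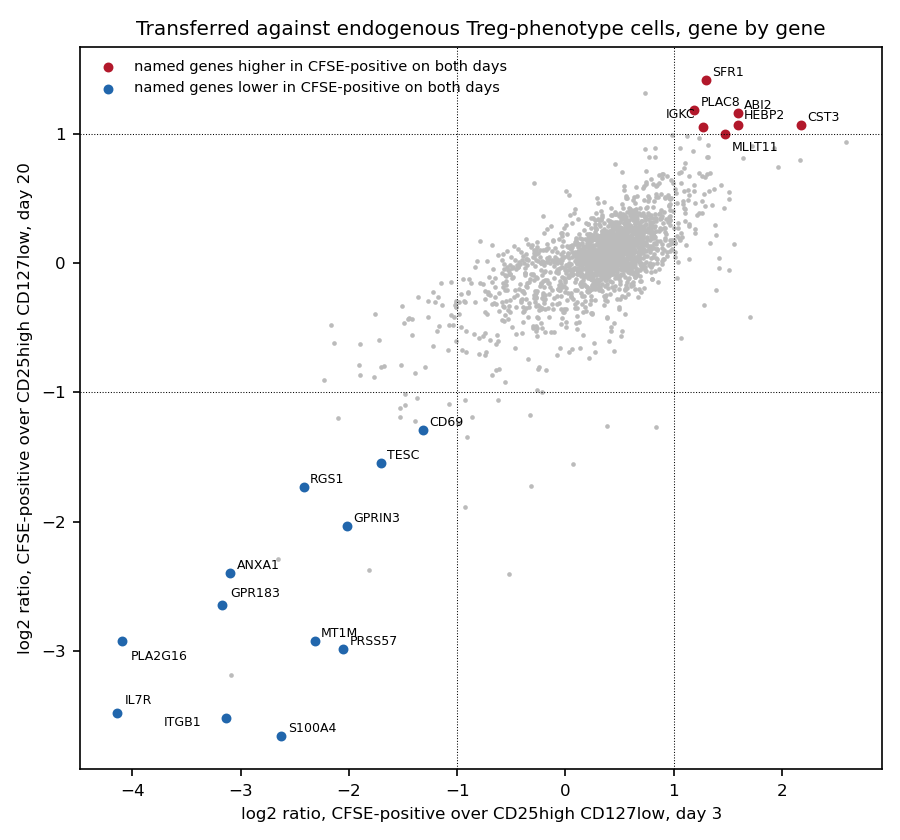
Log2 ratio of CPM (pseudocount of 10) in CFSE-positive over CD25high CD127low cells on day 3 (x axis) and day 20 (y axis), with 1 grey point per gene at 50 CPM or more on each day and dotted lines at 2-fold. The 12 lower genes named by rule are blue, IL7R among them at -4.14 and -3.48, and the 7 higher ones are red, CST3 among them at 2.18 and 1.07.

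Transferred cells were next set against CD127-positive CD25-negative cells, which represent conventional CD4 cells. FOXP3 was at 0.53 CPM (0.144 to 1.36) in conventional cells on day 3 and 0.246 CPM (0.0298 to 0.888) on day 20, with log2 ratios of 4.67 and 3.74 for transferred over conventional cells. IL2RA (ENSMMUG00000015151) encodes CD25, on which the conventional cells were sorted, and stood at 634 CPM (620.3 to 649) against 5.44 CPM (3.90 to 7.37) on day 3. CD40LG (ENSMMUG00000013773), the helper T cell ligand that activates B cells, was lower in transferred cells, at 2.47 CPM (1.67 to 3.52) against 56.9 CPM (51.6 to 62.5) on day 3 and 1.67 CPM (0.542 to 3.90) against 84.5 CPM (78.3 to 91.1) on day 20. GZMB (ENSMMUG00000014381), a cytotoxic granule protease, was also lower, at 26.2 CPM (23.4 to 29.2) against 682 CPM (664 to 701) on day 3.

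On both days 34 genes were at least 2-fold higher and 31 at least 2-fold lower in transferred than in conventional cells, of 1913. All-gene medians were 0.52 on day 3 and 0.11 on day 20. TMM scaling moved the day 3 median by -0.33 and gave 16 higher and 39 lower, median-of-ratios factors gave 18 and 39, and named-gene scaling gave 26 and 38. The named genes kept their 2-fold difference on both days under these 3 scalings. Besides FOXP3 and IL2RA, the higher genes included CD9, a tetraspanin, CSF1, a macrophage growth factor, TNFRSF18, the co-stimulatory receptor GITR, IGKC, NAA15, CLDND1, DPEP2, PTMS and SLC25A4. CD9 had log2 ratios of 3.52 and 2.92, and CLDND1 of 2.72 and 2.19. Besides IL7R, GZMB and CD40LG, the lower genes were ID2, an inhibitor of E proteins, NKG7, a granule protein, TYROBP, a signalling adaptor of natural killer cells, CCL4L1, a chemokine, SERPINA1, a protease inhibitor, PLA2G16, ANXA1, S100A4 and ITGB1. ID2 had log2 ratios of -4.27 and -4.13, and NKG7 of -2.69 and -3.32.

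By list, Treg core genes were higher on both days, at 1.22 (random median 0.49, percentile 100) with 9 of 15 measured members at least 2-fold higher and 0 at least 2-fold lower on day 3 and 0.75 (random median 0.10, percentile 100) with 5 of 12 measured members at least 2-fold higher and 0 at least 2-fold lower on day 20. Examples besides FOXP3 were CTLA4 at 1.15 and 0.81 and TNFRSF18 at 2.75 and 1.53. Cytotoxic genes were lower, at -2.31 (random median 0.54, percentile 0) with 0 of 6 measured members at least 2-fold higher and 6 at least 2-fold lower on day 3 and -1.67 (random median 0.15, percentile 0) with 0 of 8 measured members at least 2-fold higher and 7 at least 2-fold lower on day 20. Naive genes were lower at -0.63 (random median 0.52, percentile 0.04) and -0.27 (random median 0.11, percentile 0), with TCF7 at -1.94 and -1.73. That list holds IL7R, the gene of CD127, on which the conventional cells were sorted. IL-2 and STAT5 response genes were higher on day 3 at 1.01 (random median 0.48, percentile 99.8) and lower on day 20 at -0.42 (random median 0.11, percentile 0.01), with CISH at 2.40 and -1.61. Pro-apoptotic genes were higher at 1.68 (random median 0.52, percentile 99.8) and 1.03 (random median 0.09, percentile 100) over 3 measured members, 1 of which was below 0 on day 20. The p53 targets were higher on day 3 at 1.33 (random median 0.44, percentile 100). On day 20 they lay within the central 95%, at 0.31 (random median 0.12, percentile 93.3). Homing genes were lower at -0.75 (random median 0.54, percentile 0.1) and -0.29 (random median 0.14, percentile 0.03), although members went both ways, with 2 of 9 measured members at least 2-fold higher and 3 at least 2-fold lower on day 3 and 2 of 9 measured members at least 2-fold higher and 2 at least 2-fold lower on day 20. Immediate early genes were lower on day 3 at -0.37 (random median 0.61, percentile 1.37). On day 20 interferon response genes were higher at 0.27 (random median 0.10, percentile 97.8) and heat shock genes lower at -0.14 (random median 0.11, percentile 1.95). By the mean, interferon response (percentile 74.6), heat shock (35.6) and, on day 20, IL-2 and STAT5 response genes (9.26) lay within the central 95%, as did interferon response genes in matching classes (52.9).

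**Figure D2:**
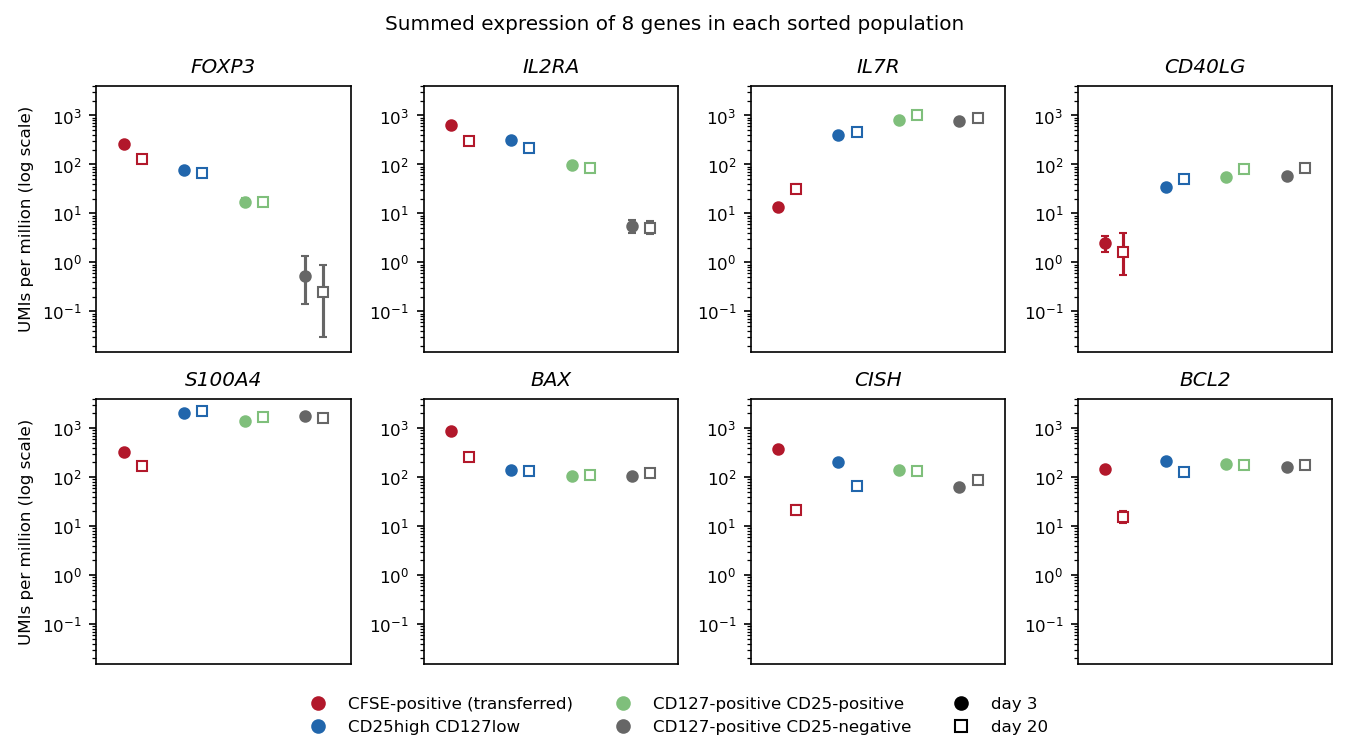
CPM (y axis, log scale) of FOXP3, IL2RA, IL7R, CD40LG, S100A4, BAX, CISH and BCL2 in the 4 sorted populations (x axis), with filled circles for day 3, open squares for day 20 and bars for exact 95% Poisson intervals. CISH in CFSE-positive cells was 379 CPM on day 3 and 21.7 CPM on day 20, while CD40LG in those cells was under 3 CPM on both days.

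CD25high CD127low and CD127-positive CD25-negative cells gave the reference contrast between the endogenous Treg and conventional phenotypes within each day. FOXP3 had log2 ratios of 3.03 on day 3 and 2.92 on day 20, and the sort marker gene IL2RA of 4.41 and 3.87. PRSS57 (ENSMMUG00000021555), a serine protease of granules, was 68.3 CPM (63.5 to 73.4) in CD25high CD127low cells and 1.06 CPM (0.458 to 2.09) in conventional cells on day 3. GZMB was lower in CD25high CD127low cells, at 23.9 CPM (21.1 to 27.0) on day 3 and 45.9 CPM (40.9 to 51.4) on day 20. IL7R, whose product CD127 was low in this sort, still had 404 CPM (392 to 416) against 781 CPM (762 to 802) in conventional cells on day 3.

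Of 1755 genes, 13 were at least 2-fold higher and 12 at least 2-fold lower on both days. The higher genes named by rule were IL2RA, FOXP3, PRSS57, CD9, LMNA, a nuclear lamin, PTTG1, a mitotic securin, NAA15, DPEP2, TNFRSF18, PTMS, TNFRSF1B, a tumor necrosis factor receptor, and SAMSN1, an adaptor of lymphocytes. LMNA had log2 ratios of 2.05 and 2.20, and SAMSN1 was under 2-fold on day 3 with named-gene scaling. Lower genes were GZMB, NKG7, CCL4L1, ID2, KLRB1, TYROBP, GNLY, PLAC8, GZMM, CST7 and SCML4, several of which belong to cytotoxic cells. Treg core genes were higher at 0.93 (random median 0.08, percentile 100) and 0.99 (random median 0.05, percentile 100), with 6 of 12 measured members at least 2-fold higher and 0 at least 2-fold lower on day 20. Cytotoxic genes were lower at -2.24 (random median 0.09, percentile 0) and -1.81 (random median 0.09, percentile 0). Activation and effector memory genes were higher at 0.51 (random median 0.06, percentile 100) and 0.56 (random median 0.06, percentile 100), including ITGB1 at 0.73 and 0.97. Interferon response genes were higher at 0.45 (random median 0.06, percentile 100) and 0.50 (random median 0.05, percentile 100), including ISG15, a ubiquitin-like interferon product, at 1.13 and 0.69. In matching classes interferon response genes were within the central 95% on both days, at percentiles 69.0 and 91.7. Heat shock genes were higher on day 3 at 0.49 (random median 0.11, percentile 99.5), but not by the mean, and naive genes lower on day 20 at -0.23 (random median 0.06, percentile 0). IL-2 and STAT5 response genes were higher on day 3 at 0.51 (random median 0.11, percentile 100) and lower on day 20 by the median, at -0.33 (random median 0.04, percentile 0), although the mean of the same members on day 20 was 0.54, with IL2RA at 3.87. In cells of the authors' matching classes 40 genes were higher and 20 lower, with CST7 under 2-fold at -0.83 on day 20, and named-gene scaling moved the all-gene median on day 3 by -0.13.

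The CD127-positive sorts differ by CD25, and their comparison asked what accompanies CD25 among CD127-positive cells. IL2RA, the CD25 gene itself, was 97.0 CPM (90.7 to 104) against 5.44 CPM (3.90 to 7.37) on day 3. FOXP3 was 17.3 CPM (14.7 to 20.3) in CD25-positive cells on day 3 and 16.9 CPM (14.5 to 19.6) on day 20, with log2 ratios of 1.38 and 1.39, but stayed under 50 CPM. GZMB was lower in CD25-positive cells, at 7.82 CPM (6.10 to 9.89) against 682 CPM (664 to 701) on day 3. Of 1657 genes, IL2RA and LMNA were the 2 at least 2-fold higher on both days, and 10 were lower, namely GZMB, NKG7, CCL4L1, CST7, ID2, GZMM, GNLY, KLRB1, TYROBP and PLAC8. LMNA had log2 ratios of 1.46 and 2.02, and GNLY, a pore-forming granule peptide, of -2.45 and -1.76.

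Cytotoxic genes were lower in CD127-positive CD25-positive cells, at -2.46 (random median 0.01, percentile 0) with 0 of 6 measured members at least 2-fold higher and 6 at least 2-fold lower and -1.81 (random median 0.06, percentile 0) with 0 of 8 measured members at least 2-fold higher and 8 at least 2-fold lower. Smaller differences were higher activation and effector memory genes, at 0.25 (random median 0.00, percentile 100) and 0.30 (random median 0.04, percentile 100), and higher interferon response genes, at 0.26 (random median 0.01, percentile 100) and 0.33 (random median 0.05, percentile 100). ANXA1 had log2 ratios of 0.21 and 0.30, and MX1 of 0.44 and 0.55. On day 3 Treg core genes were higher at 0.14 (random median -0.02, percentile 98.9), against 0.09 (random median 0.04, percentile 79.2) on day 20. Also on day 3, IL-2 and STAT5 response genes were higher at 0.21 (random median 0.00, percentile 99.6), with CISH at 1.05, while naive genes were lower at -0.17 (random median 0.00, percentile 0.97). The Treg core and the IL-2 and STAT5 response lists both hold IL2RA, the CD25 gene by which these sorts differ. These 2 list results are thus partly the sort marker itself. On day 20 glycolysis genes were higher at 0.20 (random median 0.05, percentile 97.7). In Tconv cells Treg core (percentile 64.9) and glycolysis genes lay within the central 95%, and by the mean naive genes and glycolysis genes (86.3) did. With TMM, median-of-ratios and named-gene scaling the named genes kept their 2-fold differences.

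Comparing day 20 with day 3 in each population asked what changed with time after transfer, but each day is a different library, so day and library are confounded. CFSE is also diluted at division, so transferred cells that divided most may be missing from the CFSE-positive sort of day 20. This was not tested. CISH (ENSMMUG00000010497), a STAT5 target, was lower on day 20 in transferred cells, at 21.7 CPM (16.8 to 27.7) against 379 CPM (368 to 390.0). BCL2 (ENSMMUG00000037487), which protects T cells from apoptosis, stood at 15.7 CPM (11.5 to 20.9) against 149 CPM (143 to 157). BAX (ENSMMUG00000003907) was 262 CPM (244 to 281) against 894 CPM (878 to 911), and SOCS1, another inhibitor of cytokine signalling, had a log2 ratio of -1.65. FOXP3 was lower on day 20 at -0.97 and IL2RA at -1.03. CD48 (ENSMMUG00000015812), an adhesion receptor of lymphocytes, was higher on day 20, at 483 CPM (458 to 508) against 75.6 CPM (70.7 to 80.6). IFI6, an interferon-induced protein, was higher at 2.08, and NPM1, a nucleolar chaperone, at 1.58.

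In transferred cells 91 genes were at least 2-fold higher and 69 at least 2-fold lower on day 20, of 2227, around an all-gene median of -0.33. The day 3 library stood apart from the other 7 in its ribosomal protein share of UMIs, 31.2% against 39.0 to 42.6%, and its median genes per cell, 1045 against 714 to 895. Doublet-like cells or cells with markers of other types made up 8.43% of it and 1.22% of the day 20 library. Of the 91, 76 were ribosomal, mitochondrial or unnamed. TMM scaling moved the all-gene median by 0.14 and gave 109 higher and 36 lower, median-of-ratios factors gave 116 and 34, and named-gene scaling gave 143 and 23. Against the median of the other 3 populations' own day ratios, 86 of the 91 and 60 of the 69 were also at least 2-fold apart. That was largely built in, since the genes were chosen by the same CFSE-positive ratio. Few genes differed 2-fold between days in the CD127-positive sorts, 0 higher and 2 lower in CD25-positive and 1 higher and 2 lower in CD25-negative cells. Other named genes higher on day 20 were PFDN5, a chaperone subunit, SEPT1, CASP12, SLC2A11, NACA2, DAD1 and C9orf16. Lower ones were DRA, an MHC class II chain, at -2.21, APOBEC3H, an antiviral deaminase, at -1.82, CD70, a co-stimulatory ligand, at -1.68, HEMK1, HBB and HBQ1. HBB and HBQ1 are globin genes, and HBQ1 had a log2 ratio of -2.42 that became 0.04 without doublet-like cells, a step that removes cells with globin UMIs.

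By list, IL-2 and STAT5 response genes were lower on day 20 in transferred cells, at -1.28 (random median -0.31, percentile 0) with 0 of 8 measured members at least 2-fold higher and 5 at least 2-fold lower, CISH, BCL2 and SOCS1 among them. Treg core genes were lower at -0.73 (random median -0.31, percentile 0), p53 targets at -1.17 (random median -0.25, percentile 0), and activation and effector memory genes at -0.49 (random median -0.26, percentile 2.25). Glycolysis genes were lower at -0.67 (random median -0.34, percentile 0.27), with LDHA, a lactate dehydrogenase chain, at -0.95. Naive and quiescent genes were higher on day 20 at 0.41 (random median -0.28, percentile 100), with TCF7 at 0.34. Interferon response genes were higher at 0.26 (random median -0.31, percentile 99.9), with IFI6 the 1 of 10 measured members at least 2-fold higher. That list was above random lists between days in the other sorts too, so its rise was not confined to transferred cells. It stood at 0.24 (random median 0.04) in CD25high CD127low and 0.24 (random median 0.13) in CD127-positive CD25-positive cells. Homing genes were higher at 0.07 (random median -0.30, percentile 98.9). Activation genes with TMM factors (percentile 3.08), and homing genes by the mean (91.6) and in the transTreg class (97.2), were within the central 95%. Anti-apoptotic genes as a list were at -0.34 (random median -0.25, percentile 26.8) and oxidative phosphorylation genes at -0.34 (random median -0.36, percentile 56.1), within the central 95% of random lists.

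CD25high CD127low cells had 47 genes at least 2-fold higher and 6 at least 2-fold lower on day 20, of 1854, and 43 of the 47 were unnamed, ribosomal or mitochondrial. With TMM factors 24 and with median-of-ratios factors 23 of the 47 were higher, and 6 were lower with either. CGA, the alpha chain of glycoprotein hormones, was 156 CPM (146 to 165) on day 20 against 48.6 CPM (44.5 to 52.9) on day 3. The other named higher genes were MBD3, a chromatin protein, at 1.13, MT1M at 1.10 and PCBP1, an RNA-binding protein, at 1.08. CISH was lower at -1.51, ID2 at -1.15, AIRE, a transcriptional regulator of self-antigens, at -1.03 and LPAR6, a lysophosphatidic acid receptor, at -1.01, besides the globin genes HBB and HBQ1. Median-of-ratios factors moved the all-gene median by -0.11. PCBP1 with these factors and LPAR6 with named-gene scaling were under 2-fold, and HBQ1 had a log2 ratio of -4.35 that became 0.07 in cells of the endoTreg class. Members of the IL-2 and STAT5 response list were lower at -0.67 (random median 0.00, percentile 0) and heat shock genes at -0.37 (random median 0.05, percentile 0.02). Cytotoxic genes were higher at 0.53 (random median 0.09, percentile 99.4) and interferon response genes at 0.24 (random median 0.04, percentile 98.9). Within the endoTreg class alone these medians were 0.15 (percentile 60.1) and 0.22 (percentile 97.3), both inside the central 95%. Interferon response genes were also inside it without doublet-like cells (percentile 91.4) and by the mean of their members.

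In CD127-positive CD25-positive cells 0 genes were higher and 2 lower on day 20, of 1780, namely HBB at -3.93 and the unnamed LOC710665 at -1.07, chosen after its value was seen. TMM scaling moved the all-gene median of this contrast by -0.12 and gave 11 lower. Naive genes were higher at 0.23 (random median 0.12, percentile 99), activation and effector memory genes at 0.16 (random median 0.08, percentile 99.1) and interferon response genes at 0.24 (random median 0.13, percentile 98.9), with IFI27, an interferon-induced protein, at 0.61. In the Tconv class naive genes (percentile 97.2) and activation genes (97.17) were just inside the central 95%, and naive genes also without doublet-like cells (91.6). Treg core genes stood at 0.00 (random median 0.13, percentile 0.6) and IL-2 and STAT5 response genes at -0.07 (random median 0.12, percentile 0.79), both below the random lists. By the mean they lay at percentiles 19.1 and 8.43, and in the Tconv class at 31.2 and 36.6, within the central 95%. Conventional cells had DRA higher, at 1.06, and HBB and HBQ1 lower, at -5.01 and -3.01, of 1748 genes. DRA was under 2-fold with a pseudocount of 30 CPM (0.75), with per-cell mean CPM (0.97), without doublet-like cells (0.89) and in the Tconv class (0.32), and without doublet-like cells no gene passed. Interferon response genes were higher at 0.23 (random median 0.08, percentile 100), including ISG15 at 0.48, heat shock genes were higher at 0.25 (random median 0.03, percentile 100), and immediate early genes lower at -0.32 (random median 0.07, percentile 1.11). CISH was close between days in these sorts, at -0.09 in CD127-positive CD25-positive and 0.39 in CD127-positive CD25-negative cells.

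**Figure D3:**
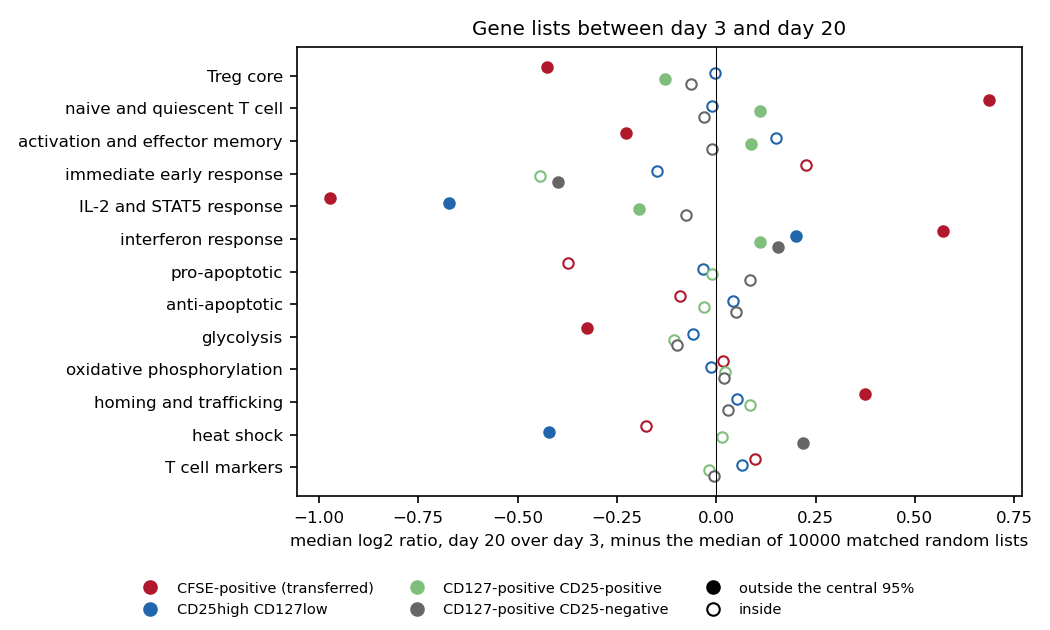
Median log2 ratio of day 20 over day 3 of each gene list minus the median of 10000 matched random lists (x axis) for 13 lists (y axis), with 1 colour per sorted population and filled points outside the central 95% of random lists. IL-2 and STAT5 response genes had a median of -1.28 in CFSE-positive and -0.67 in CD25high CD127low cells, against -0.07 in CD127-positive CD25-positive cells.

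Similarity of whole libraries was measured as Spearman correlation over 4418 genes, which are not independent replicates. CFSE-positive cells correlated with CD25high CD127low cells at 0.888 on day 3 and 0.933 on day 20, and with conventional cells at 0.800 and 0.909. CD25high CD127low cells correlated with conventional cells at 0.938 and 0.949. Between days the coefficients were 0.904 for CFSE-positive, 0.958 for CD25high CD127low, 0.971 for CD127-positive CD25-positive and 0.979 for conventional cells. Genes that marked CD25high CD127low against conventional cells on 1 day were then measured on the other day. The 27 genes higher on day 3, FOXP3 and IL2RA among them, had a median log2 ratio of 0.42 in transferred over conventional cells on day 20, against 1.12 in CD25high CD127low cells and an all-gene median of 0.11. With a 3-fold limit, 8 genes remained, with a median of 1.53 in transferred over conventional cells. The 27 genes higher on day 20 had a median of 1.61 in transferred over conventional cells on day 3, where the all-gene median was 0.52, and -0.21 over CD25high CD127low cells. They went both ways, with 15 at least 2-fold higher and 8 at least 2-fold lower in transferred than in conventional cells. Of these 27, 10 passed the 3-fold limit, at 2.33 over conventional and 1.03 over CD25high CD127low cells, the latter opposite in sign to -0.21. The 36 genes lower on day 3 had a median of -0.03 in transferred and 0.25 in CD25high CD127low over conventional cells on day 20, while the 9 of them at 3-fold stood at -2.61 in transferred cells. The 13 lower on day 20, GZMB among them, had medians of -2.58 and -1.90 on day 3. Several of these, GZMB, NKG7 and GNLY among them, were also lower in CD127-positive CD25-positive than in conventional cells. They therefore do not mark the Treg phenotype alone.

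Shares of cells with at least 1 UMI of a gene are given as found and after thinning each cell to 1000 UMIs, with exact 95% binomial intervals. FOXP3 was found in 46.5% (45.0 to 48.1%) of CFSE-positive cells on day 3 and 25.4% (22.9 to 28.0%) on day 20, or 22.1% and 11.1% after thinning. In CD25high CD127low cells the shares were 16.1% (14.9 to 17.4%) and 13.4% (12.05 to 14.8%), or 6.90% and 6.32% after thinning. CD127-positive CD25-positive cells had 3.25% (2.64 to 3.96%) and 2.82% (2.37 to 3.33%), or 1.49% and 1.77% after thinning. The background, from CD127-positive CD25-negative cells, was 0.132% (0.0359 to 0.337%) and 0.0544% (0.0066 to 0.196%), or 0.0329% and 0.0272% after thinning. Median depths behind these shares were 2796 and 2588 UMIs in CFSE-positive, 3095 and 2674 in CD25high CD127low, 2942 and 2131 in CD127-positive CD25-positive and 2445 and 2185 in conventional cells on day 3 and day 20. Thinning left out 17 CFSE-positive cells of day 3, 6 CD127-positive CD25-positive and 6 conventional cells of day 20, and 0 elsewhere.

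CTLA4 was found in 9.95% (9.05 to 10.9%) of CFSE-positive and 12.6% (11.5 to 13.8%) of CD25high CD127low cells on day 3, or 3.68% and 4.75% after thinning, against 0.922% in thinned conventional cells. These shares are of whole sorts. In CPM the gap was wider between the transTreg and endoTreg classes, which keep unlike parts of their sorts. CD40LG was found in 0.579% (0.372 to 0.861%) of CFSE-positive cells on day 3 and 0.435% (0.141 to 1.01%) on day 20, or 0.267% and 0.087% after thinning. Conventional cells had 12.7% (11.5 to 13.9%) and 16.1% (14.95 to 17.4%), or 5.89% and 8.12% after thinning. GZMB was found in 20.9% (19.4 to 22.4%) of conventional cells on day 3, or 18.3% after thinning, against 3.02% (2.52 to 3.59%) and 1.77% of CFSE-positive cells. MKI67, a marker of dividing cells, was found in 2.32% (1.88 to 2.82%) of CFSE-positive cells on day 3 and 0.435% (0.141 to 1.01%) on day 20, or 0.921% and 0.261% after thinning, with 0.0988% and 0.0817% in thinned conventional cells. The CFSE-positive shares cover only cells that still held the dye.

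The authors' annotation gave each cell 1 of 3 classes, so their sizes are values of the annotation and not independent results. In each library the transTreg class matched clusters 1 and 2 together in size, and the endoTreg class clusters 3 and 4. The classes thus appear to follow the authors' clusters, whose method is not stated, and not the sort alone. Marker differences between classes may therefore be partly built in. The transTreg class held 4079 of the CFSE-positive cells on day 3 (98.5%) and 1064 on day 20 (92.6%). The authors' clusters split these days, with 4071 of the 4142 CFSE-positive cells of day 3 in cluster 1 and 1018 of the 1149 of day 20 in cluster 2. The endoTreg class held 1301 of the CD25high CD127low cells on day 3 (38.9%) and 938 on day 20 (40.0%), and the Tconv class 2037 (60.9%) and 1356 (57.9%). A further 9 cells (0.27%) on day 3 and 49 (2.09%) on day 20 of that sort were in the transTreg class. Within CD25high CD127low cells of day 3 FOXP3 was 160.2 CPM (149 to 172) in the endoTreg class and 17.5 CPM (14.4 to 21.1) in the Tconv class, and IL7R 145 CPM (134 to 157) and 585 CPM (566 to 604). Finer names put 1124 of the CFSE-positive cells of day 3 in an effector class (27.1%), 2687 in a transition class (64.9%) and 123 in a naive class (2.97%), against 0, 57 (4.96%) and 985 (85.7%) on day 20. With 1 library per group, a class held mostly by 1 library may be that library rather than a cell type.

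Of the 30 gene lists fixed beforehand, 15 had under 3 measured members, at 20 CPM or more, in every comparison and give no list result. The most members measured were 1 for T helper cytokines and CD40LG, Th1, Th2 and MHC class II genes, and 2 for proliferation, co-inhibitory receptor, monocyte, B cell, natural killer cell and erythroid genes. None were measured for Tfh, CD8 T cell, platelet, dendritic cell and gamma delta T cell genes. CD4 itself stood at 7.29 CPM in conventional cells of day 3, and JUND at 0, MCL1 at 1.33 and CCL5 at 0.795, genes that T cells usually express, and the files do not show how far the gene models used for counting cover them.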

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

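The test of the STAT5 list against RNA shared by all libraries of a day was chosen only after the result was seen. Results were picked out here when the same contrast went opposite ways between populations or days, and none of these differences was tested. IL-2 and STAT5 response genes in transferred over conventional cells had a median log2 ratio of 1.01 (random median 0.48, percentile 99.8) on day 3 and -0.42 (random median 0.11, percentile 0.01) on day 20. CD25high CD127low over conventional cells gave 0.51 (random median 0.11, percentile 100) and -0.33 (random median 0.04, percentile 0) for the same list. The mean of its members on day 20 was 0.54 (percentile 98.9). IL2RA, which encodes the sort marker CD25, was the 1 of 7 measured members at least 2-fold higher. The opposite sign between days thus held for the median, but not for a mean that includes this sort marker gene. CISH alone stood at 2.40 on day 3 and -1.61 on day 20 in transferred over conventional cells.

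Treg core genes in transferred over CD25high CD127low cells were at 0.59 (random median 0.39, percentile 97.6) on day 3 and -0.17 (random median 0.06, percentile 0.36) on day 20. In cells of the authors' matching classes the day 3 median was 0.14 (percentile 5.71), below its random median. DRA, an MHC class II chain, was 1.24 on day 3 and -2.03 on day 20 in transferred over conventional cells. Its day 20 over day 3 ratio was -2.21 in CFSE-positive and 1.06 in CD127-positive CD25-negative cells, and 0.32 in the Tconv class of the latter. Activation and effector memory genes had day ratios of 0.16 (random median 0.08, percentile 99.1) in CD127-positive CD25-positive and -0.49 (random median -0.26, percentile 2.25) in CFSE-positive cells. The former was at percentile 97.17 in the Tconv class and the latter at 3.08 with TMM factors, both within the central 95%. Heat shock genes had day ratios of 0.25 (random median 0.03, percentile 100) in CD127-positive CD25-negative and -0.37 (random median 0.05, percentile 0.02) in CD25high CD127low cells.

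The difference between days in IL-2 and STAT5 response genes was weighed further. RNA differing between all libraries of the days would lower the list in the CD127-positive sorts too, but the lower of their medians was -0.0745, which argues against it as the whole cause. That median, in CD127-positive CD25-positive cells, was still below its random median of 0.12 (percentile 0.79), so a small part of this kind is not excluded. A different mix of the authors' classes in the CD25high CD127low sort was argued against by the endoTreg class alone, where the median was -0.84 with 6 of 8 members below -0.3, and library scaling by the TMM median of -1.13 in CFSE-positive cells, with 8 of 8 members below -0.3. A candidate explanation that stays open is cytokine signalling that was stronger in Treg-phenotype cells on day 3, which no label addresses and which 1 library per day does not separate from other differences between the libraries.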

How the results depend on the processing

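The alternatives with the authors' classes, named-gene scaling and named-gene similarity were chosen only after the result was seen. Of 252 alternative values of counts, list totals, similarities, signatures and FOXP3 shares, 177 stayed within the limits set and 75 moved. Single genes gave 1274 of 1580 within limits, 304 moved and 2 with the opposite sign, and medians of single lists 630 of 692, with 60 moved and 2 reversed. Shares of other genes moved in 65 of 72 cases, since thinning reads fewer UMIs per cell. Signature values against endogenous cells gave 4 of 8 within limits, 3 moved and 1 reversed. Unless a cause follows from how an alternative is built, the cause was not tested.

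With TMM factors 3 genes were higher in transferred over endogenous cells (7 in the main result), 16 in transferred over conventional cells (34), and 24 on day 20 in CD25high CD127low cells (47), while 36 (69) were lower on day 20 in CFSE-positive and 11 (2) in CD127-positive CD25-positive cells. Median-of-ratios factors gave 3, 18, 23, 34 and 11 for the same counts. Named-gene scaling gave 3 higher in transferred over endogenous cells, 143 higher (91) and 23 lower on day 20 in CFSE-positive cells, and 11 lower in CD127-positive CD25-positive cells. A pseudocount of 1 CPM gave 12 higher in transferred over endogenous cells, 8 lower on day 20 in CD127-positive CD25-positive and 4 (2) lower in CD127-positive CD25-negative cells. A pseudocount of 30 CPM, which shrinks the ratios of low genes, gave 1 and 14 higher in transferred over endogenous and conventional cells and 8 (13) higher in endogenous over conventional cells. On day 20 it gave 59 higher and 33 lower in CFSE-positive, 15 higher and 3 (6) lower in CD25high CD127low, and 0 (1) higher in CD127-positive CD25-negative cells.

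Without the expression filter, which admits genes of few UMIs, 24 genes were higher and 50 (23) lower in transferred over endogenous, 70 higher and 57 (31) lower in transferred over conventional, 23 higher and 21 (12) lower in endogenous over conventional, and 4 (2) higher and 21 (10) lower in CD127-positive CD25-positive over CD25-negative cells. On day 20 it gave 1 (0) higher and 4 (2) lower in CD127-positive CD25-positive and 2 (1) higher in CD127-positive CD25-negative cells. Without doublet-like cells 1 gene was lower on day 20 in CD127-positive CD25-positive cells, and 0 were higher and 0 lower in CD127-positive CD25-negative cells. There HBQ1 in CFSE-positive cells was 0.0438 (-2.42) between days, as cells with globin UMIs are removed, 2 (1) lists lay below random on both days in endogenous over conventional cells, and 1 (2) above random between days in CD25high CD127low cells. Thinned library totals gave 5 lower on day 20 in CD127-positive CD25-positive cells and 5 in CD127-positive CD25-negative cells. Per-cell mean CPM gave 0 higher in CD127-positive CD25-negative cells.

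In cells of the authors' matching classes 40 (13) genes were higher and 20 (12) lower in endogenous over conventional cells, and 0 (1) higher on day 20 in CD127-positive CD25-negative cells. HBQ1 between days in CD25high CD127low cells was 0.0713 (-4.35), and the Treg core median of transferred over endogenous cells on day 3 was 0.14 (0.59), below its random median. With these classes 0 (1) lists lay above random on both days in transferred over endogenous cells, 2 (1) below on both days in endogenous over conventional cells, 0 (2) above between days in CD25high CD127low cells, and 1 (3) above and 0 (2) below between days in CD127-positive CD25-positive cells. List means in place of medians gave 5 (2) lists below random on both days in transferred over endogenous cells, 4 (2) above on both days in CD127-positive CD25-positive over CD25-negative cells, 1 (2) above between days in CD25high CD127low cells, and 0 (2) below between days in CD127-positive CD25-positive cells. IL-2 and STAT5 response genes in endogenous over conventional cells on day 20 had a mean of 0.54 against a median of -0.33. That mean includes the sort marker gene IL2RA.

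Pearson correlation was 0.942 and 0.971 for CFSE-positive with CD25high CD127low cells on day 3 and day 20, and 0.892 and 0.960 with CD127-positive CD25-negative cells. Thinned totals gave 0.879 and 0.792 for these pairs on day 3. Named genes only gave 0.928 with CD25high CD127low cells on day 20, and 0.822 and 0.897 with CD127-positive CD25-negative cells on day 3 and day 20. A 3-fold signature, with fewer genes, gave medians in transferred over conventional cells of 1.53 (0.42) and -2.61 (-0.03) for the 8 genes higher and 9 lower on day 3, and 2.33 (1.61) for the 10 higher on day 20, which stood at 1.03 (-0.21) over endogenous cells. FOXP3 shares after thinning were 22.1% and 11.1% in CFSE-positive cells on day 3 and day 20, 6.90% and 6.32% in CD25high CD127low, 1.49% and 1.77% in CD127-positive CD25-positive, and 0.0329% on day 3 in CD127-positive CD25-negative cells, because fewer UMIs are read per cell. Genes under 20 CPM were left out of lists, so depth limits what they cover. The planned change of Leiden resolution was not run because the authors' annotation was used. No result came from a test, and a model with day as a block over the 8 libraries was not run.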

Other observations

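The tests of the p53 pattern against a few cells, library scaling and dying cells were chosen only after the result was seen, and so were the p53 list and the genes named in this part.

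BAX led to a check of p53 target genes in CFSE-positive cells of day 3, where BAX was 894 CPM (878 to 911) and CDKN1A 32.4 CPM (29.3 to 35.8), against 140.4 CPM (133 to 148) and 4.91 CPM (3.68 to 6.43) in CD25high CD127low cells. A few cells of very high expression were argued against by the shares of cells with a UMI, whose median ratio over the members was 2.29 after thinning, over 1.2 in 8 of 9 members. Library scaling as the whole cause was argued against by the TMM median of 0.79, with 8 of 9 members above 0.2, SESN1 being the exception. A p53 response may explain the pattern, but a second list held 1 member at 20 CPM or more (CCNG1, 455 against 215 CPM), which was too few to decide. CCNG1 was also a member of the first list, so it was no independent check. Dying cells could not be judged either, since the ratio of median mitochondrial shares was 0.993 in cells that end at 5%.

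IL7R was examined in CD25high CD127low cells, whose sort selected low CD127. Cells with a FOXP3 UMI had 147 CPM (129.9 to 165) on day 3 and 214 CPM (184 to 247) on day 20, and cells without one had 458 CPM (444 to 473) and 496 CPM (478 to 515). Free RNA as the only source would give all cells a like level and is argued against by the ratio of 3.13 on day 3. Free RNA as a part of the level is not excluded. Conventional CD4 cells within the sort may account for part of the IL7R level, since the ratio on day 20 was 2.32, although a FOXP3 UMI is missed in many cells that express the gene.

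CISH was also read by FOXP3 UMI. In CFSE-positive cells with one, CISH was 391 CPM (375 to 408) on day 3 and 14.3 CPM (7.14 to 25.6) on day 20, and without one 368 CPM (353 to 383) and 24.3 CPM (18.2 to 31.7). In CD25high CD127low cells with a FOXP3 UMI it was 324 CPM (299 to 351) and 47.2 CPM (33.7 to 64.3), and in CD127-positive CD25-positive cells with one 276 CPM (221 to 339.9) and 61.4 CPM (35.8 to 98.3). In CD127-positive CD25-positive cells without one CISH was 138 CPM (130.1 to 146) and 136 CPM (129 to 143). CD48 ranged from 75.6 to 677 CPM over the 8 libraries and PFDN5 from 45.0 to 464 CPM, while CD48 over PFDN5 stayed between 1.31 and 1.68. CD48, PFDN5 and IFI6 were each lowest in CFSE-positive cells of day 3 and highest in CD25high CD127low cells of day 20, with IFI6 at 27.0 and 284 CPM. Their day 20 rise in transferred cells thus starts from the lowest of the 8 libraries. CGA stood at 48.6 and 156 CPM in CD25high CD127low cells on day 3 and day 20, at 9.39 and 29.8 CPM in CD127-positive CD25-positive cells, and at 0.0823 and 0 CPM in CFSE-positive cells.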
